A study of Mus musculus with 69 samples.

How the data were processed

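The samples are mouse prostate organoids, profiled by bulk RNA sequencing of polyA RNA. The deposited values are estimated counts per gene, in 3 tables, with genome build mm10 per the labels. The aligner, the counting program and the gene annotation are not given in the sources used here. Between 40.8% and 46.3% of values are not whole within 0.01, as when reads that match several genes are shared among them. Library totals differ within each table, so the values had not been scaled to a common total. Each column was matched to its sample through the library code in the sample's label, and 0 columns had no matched sample.

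The TKOM table holds 16919 lines, against 18828 for PRAD and NEPC and 18996 for the genotypes. Lines without a gene name (10, 11 and 12) were left out, and they hold at most 0.0115% of a library. Lines that share a name were summed, for 15, 16 and 17 names, which left 16893, 18799 and 18966 names. Values were then rounded to whole counts. No library was left out. Library totals were 31460616 to 40458465, 22799838 to 77790816 and 18629462 to 92280307 counts in that order. The common biological coefficient of variation was 3.63%, 3.85% and 2.37%, so small fold changes pass the test at 3 libraries per group. The p-values measure only the spread between these libraries, which may be technical, since the labels do not say whether replicates are separate cultures or lines.

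Each table was fitted by itself over all of its groups with edgeR 4.0.16 (R 4.3.3) as a quasi-likelihood model of group means. Genes were kept by filterByExpr, which asks for about 10 counts in a library of median size. TMM factors scaled the libraries. This left 15733, 18483 and 18430 genes. The F-tests were 2-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the genes kept. There were 33 comparisons, of which 1, 17 and 15 fall in the TKOM, the PRAD and NEPC, and the genotype table. They cover pairs of groups, the mean of the 3 NEPC lines, and differences between effects on the log2 scale. Several comparisons share the same DMSO libraries, so no overlaps or correlations are given between those. The samples, comparisons, tests, gene lists, key genes and most of the alternatives were set before the data were examined.

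Gene lists, 24 in all, were written from general knowledge of mouse genes. They include neuroendocrine, luminal, basal, YAP/TEAD targets, YAP/TEAD components, Notch targets, Notch ligands and antagonists, extracellular matrix, integrins and focal adhesion, cell cycle, tuft cell, mesenchymal, fibroblast, immune, endothelial, neuron and glia, interferon response, antigen presentation, hypoxia and glycolysis, cholesterol synthesis, p53 targets, amino acid and ER stress and squamous and wound. For each list and comparison, limma 3.58.1 ran camera with a preset correlation of 0.01 between genes, adjusted over the 24 lists of the comparison. Camera compares the genes of a list with all other genes. Camera with an estimated correlation and fry were the alternatives. Genes named in the report and in the closing part were picked, after the values were seen, from those that a rule gave: the key genes, then for each list the 4 called members with the largest change, then for each comparison the 6 highest and 6 lowest called genes with an average log2 CPM of at least 3, groups that do not overlap (where 2 are compared) and no predicted gene name. A gene list and some genes are not reported here. Of the 118 pairings of a gene with a comparison of 2 groups, 118 have all 3 libraries of one group beyond all 3 of the other. Chance alone gives that for 10% of genes, and the rule itself selects for it.

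Levels are in CPM as edgeR computes it, which scales the counts of each library to the same TMM-adjusted total, and are given as mean ± SD over 3 libraries. A ± after a log2 fold change is its standard error from the fit. Where a group holds 0 counts, the fold change is a lower bound against a floor of 3 counts over the group, from counts pooled over libraries, written as at least that many fold. Such bounds cover counting error only. Names were matched by symbol, and the mm10 reference annotation places Yap1 on chromosome 9, 7931999 to 8004596 and Rb1 on chromosome 14, 73183673 to 73325822.

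The tests were tried on simulated data with 50 genes changed at each fold size. For Suspension D30 vs Matrigel, over 15588 genes, the share recovered was 48% at 1.2-fold, 70% at 1.5-fold, 84% at 2-fold, 96% at 4-fold, with 0.116% of unchanged genes called. For PRAD ARi D8 vs DMSO D8 (18101 genes) these were 42%, 68%, 80%, 90% and 0.0274%, in that order. For NEPC mean of 3 lines vs PRAD COMBO D42 (18104 genes) they were 64%, 82%, 82%, 92% and 0.0438%. For PRAD YAPi by NOTCHi interaction (18125 genes) they were 14%, 64%, 80%, 74% and 0.0438%. For TKO vs PtP in DMSO (17925 genes) they were 36%, 80%, 90%, 94% and 0.0604%. For COMBO effect TKO minus WT (17916 genes) they were 38%, 68%, 78%, 94% and 0.0330%. The simulation changes few genes, whereas 26.56% to 87.15% passed in the real comparisons, so these shares need not hold there. The alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, a fit of only the groups compared, replicate number as a block, and leaving out each replicate. A pair of further alternatives was chosen after seeing the data: leaving out the libraries that stand apart, and thinning the deepest libraries. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.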

Results

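Bulk RNA sequencing of polyA RNA was made from mouse prostate organoids, which are epithelial cells grown as clusters in culture. The 69 libraries form 23 groups with n = 3 libraries in each. They come in 3 count tables, and each test stays within a table. The TKOM table holds organoids kept in Matrigel, a basement membrane gel, and organoids kept in suspension to day 30. Its 6 libraries hold 31460616 to 40458465 counts. The PRAD and NEPC table holds PRAD organoids given DMSO, ARi, YAPi, NOTCHi, pairs of these or COMBO for 8 days, PRAD organoids on COMBO for 42 days, and the lines NEPC-1, NEPC-2 and NEPC-3. Its 36 libraries hold 22799838 to 77790816 counts. The genotype table holds organoids labelled WT, PtP and TKO, each with DMSO, YAPi_NOTCHi or COMBO for 8 days. Its 27 libraries hold 18629462 to 92280307 counts. The labels name the compounds only by these codes and do not say what COMBO contains. The series title asks how the extracellular matrix acts on lineage plasticity through YAP and TEAD.

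The labels do not state which genes were altered in PtP, TKO, TKOM, PRAD or NEPC organoids, so the tumour suppressor genes Trp53 and Rb1 and the oncogene Myc are given first. In DMSO, Trp53 was 169.5 CPM ± 4.23 (SD, n = 3) in WT, 51.5 CPM ± 2.42 in PtP and 65.3 CPM ± 0.435 in TKO organoids. Rb1 was 23.2 CPM ± 0.361, 20.3 CPM ± 1.34 and 22.9 CPM ± 0.483 in the same order. In PRAD organoids with DMSO, Trp53 was 15.3 CPM ± 0.159 and Rb1 21.1 CPM ± 2.01. Myc was 982 CPM ± 39.4 in TKOM organoids in Matrigel, 78.1 CPM ± 3.92 in PRAD organoids with DMSO and 404 CPM ± 4.13 in WT organoids with DMSO. Levels set side by side across tables come from separate tables and were not tested against each other. A level of RNA over a whole gene does not show whether part of the gene was deleted.

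The TKOM comparison sets suspension at day 30 against Matrigel, whose day is not given, so time and matrix cannot be told apart. Insm1, a transcription factor of endocrine and neuroendocrine cells, rose from 0.0792 CPM ± 0.0643 (SD, n = 3) to 22.4 CPM ± 0.697 (adjusted p = 1.76e-16). Foxa2, a transcription factor of the same cells, rose from 0.0254 ± 0.0440 to 8.64 CPM ± 0.427. Trp63, which maintains basal cells, fell from 97.4 CPM ± 0.396 to 0 counts. The basal keratin gene Krt5 fell from 1449 CPM ± 62.3 to 13.7 CPM ± 1.94. Wwtr1, which encodes the YAP paralog TAZ, fell from 51.3 CPM ± 2.12 to 1.01 CPM ± 0.234, a log2 fold change of -5.65 ± 0.10 (SE). Yap1 fell from 247 CPM ± 1.57 to 182 CPM ± 3.29. Among genes with the largest falls were the receptor tyrosine kinase Axl, from 73.5 ± 3.41 to 0.0194 CPM ± 0.0170, the caveolar gene Cav1, from 136 ± 1.76 to 0.196 CPM ± 0.0447, and the laminin gene Lama3, from 73.9 ± 3.38 to 0.0777 CPM ± 0.0678.

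For each gene list, the median is that of log2 fold changes, and the counts adjusted over the list alone give those that rose, then those that fell. Genes with 0 counts in a group enter some medians again at the bound that 3 counts over the group allow. Of the neuroendocrine genes, 11 of 12 rose and 1 fell (11 and 1 adjusted over the list alone, median 3.80, camera adjusted p = 1.91e-06, adjusted p = 0.0549 with an estimated correlation). Of the basal genes, 23 of 23 fell (0 and 23 adjusted over the list alone, median -4.36, camera adjusted p = 1.42e-70, adjusted p = 0.0549 with an estimated correlation). Of the extracellular matrix genes, 1 of 22 rose and 21 fell (1 and 21 adjusted over the list alone, median -5.57, or -5.38 with such genes at their bound, camera adjusted p = 3.29e-20, adjusted p = 0.0631 with an estimated correlation). Of the integrin and focal adhesion genes, 2 of 24 rose and 22 fell (2 and 22 adjusted over the list alone, median -1.87, camera adjusted p = 1.88e-22, adjusted p = 0.0549 with an estimated correlation). Of the YAP/TEAD targets, 1 of 19 rose, 16 fell and 2 were not called (1 and 16 adjusted over the list alone, median -2.35, camera adjusted p = 3.09e-14, adjusted p = 0.0631 with an estimated correlation). Of the squamous and wound genes, 16 of 16 fell (0 and 16 adjusted over the list alone, median -3.71, camera adjusted p = 9.17e-12, adjusted p = 0.0549 with an estimated correlation). Of the cholesterol synthesis genes, 16 of 21 rose, 2 fell and 3 were not called (16 and 2 adjusted over the list alone, median 0.57, camera adjusted p = 2.50e-07, adjusted p = 0.144 with an estimated correlation). Of the hypoxia and glycolysis genes, 4 of 21 rose and 17 fell (4 and 17 adjusted over the list alone, median -0.61, camera adjusted p = 2.83e-13, adjusted p = 0.0549 with an estimated correlation). Car9, a carbonic anhydrase induced by low oxygen, fell from 162 ± 3.13 to 2.15 CPM ± 0.544. Of the mesenchymal genes, 2 of 9 rose and 7 fell (2 and 7 adjusted over the list alone, median -3.04, camera adjusted p = 0.00649, adjusted p = 0.107 with an estimated correlation). Of the endothelial genes, 2 of 3 rose and 1 fell (2 and 1 adjusted over the list alone, median 4.72, camera adjusted p = 0.0437, adjusted p = 0.145 with an estimated correlation). Of the fibroblast markers, 2 of 2 fell (0 and 2 adjusted over the list alone, median -7.77, camera adjusted p = 0.00743, adjusted p = 0.0990 with an estimated correlation). Of the immune cell markers, 2 of 2 fell (0 and 2 adjusted over the list alone, median -3.33, camera adjusted p = 6.35e-06, adjusted p = 0.0631 with an estimated correlation). With DMSO, PRAD organoids hold Cd14 of this list at 120 CPM, Cd68 at 22.7 and its other measured genes at most at 0.130. Its changes here and below need not come from immune cells. In all, 6021 genes rose and 6119 fell of 15733 tested, 1573 and 2510 by at least 2-fold (edgeR).

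The PRAD arms ask what each agent does alone and with the others. With ARi, genes of the response to low oxygen fell: Ndrg1 from 464 CPM ± 12.3 (SD, n = 3) to 27.1 CPM ± 1.59 (log2 fold change -4.09 ± 0.04, SE, adjusted p = 8.46e-45), the oxidase Ero1a from 1203 ± 43.4 to 84.0 CPM ± 2.95 and the prolyl hydroxylase Egln3 from 1097 ± 3.37 to 77.6 CPM ± 2.85. The cochaperone gene Fkbp5 and the transcription factor gene Zbtb16 fell from 131 ± 1.57 to 24.4 CPM ± 1.73 and from 18.2 ± 1.45 to 0.0249 CPM ± 0.0216. Of the hypoxia and glycolysis genes, 21 of 21 fell (0 and 21 adjusted over the list alone, median -1.69, camera adjusted p = 1.08e-140). Of the cholesterol synthesis genes, 4 of 21 rose and 17 fell (4 and 17 adjusted over the list alone, median -0.49, camera adjusted p = 5.92e-10). Of the extracellular matrix genes, 20 of 25 rose, 2 fell and 3 were not called (21 and 2 adjusted over the list alone, median 0.61, camera adjusted p = 3.47e-06). Of the fibroblast markers, 3 of 6 rose, 0 fell and 3 were not called (3 and 0 adjusted over the list alone, median 1.54, camera adjusted p = 0.000181). The collagen gene Col12a1 rose from 7.49 ± 0.775 to 52.3 CPM ± 1.03. Notch1 rose from 155 ± 9.63 to 374 CPM ± 7.28. In all, 5009 genes rose and 5067 fell of 18483 tested, 1203 and 850 of them by at least 2-fold.

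With YAPi, Foxa2 rose from 0 counts (n = 3) to 2.99 CPM ± 0.627 (adjusted p = 9.88e-21). Pcsk1, a prohormone convertase, rose from 0 counts to 5.03 CPM ± 1.07. Ccn1 and Ccn2, matricellular genes widely used as readouts of YAP and TEAD, fell from 17 ± 0.563 to 2.78 CPM ± 0.174 and from 82.1 ± 2.12 to 15.3 CPM ± 0.532. A lower Ccn2 was not particular to YAPi. It was 33.8 CPM ± 1.47 with ARi, 19.7 ± 0.171 with NOTCHi and 4.57 ± 0.218 with ARi_NOTCHi. Ccn1 was 16.6, 13.35 and 14.4 CPM in those arms. Of the YAP/TEAD targets, 6 of 21 rose, 12 fell and 3 were not called (6 and 12 adjusted over the list alone, median -0.18, camera adjusted p = 0.237). B2m, the light chain of class I molecules, rose from 311 ± 15.7 to 1217 CPM ± 24.3. Of the neuroendocrine genes, 31 of 39 rose, 0 fell and 8 were not called (31 and 0 adjusted over the list alone, median 4.87, or 3.52 with such genes at their bound, camera adjusted p = 8.27e-09). Of the interferon response genes, 24 of 26 rose, 0 fell and 2 were not called (26 and 0 adjusted over the list alone, median 1.16, camera adjusted p = 5.77e-18). Ifit1 rose from 16.5 ± 0.729 to 80.3 CPM ± 4.50. Of the antigen presentation genes, 12 of 14 rose, 0 fell and 2 were not called (12 and 1 adjusted over the list alone, median 1.03, camera adjusted p = 4.53e-11). Of the cell cycle genes, 30 of 30 fell (0 and 30 adjusted over the list alone, median -1.16, camera adjusted p = 3.89e-45). Of the squamous and wound genes, 17 of 18 rose and 1 fell (17 and 1 adjusted over the list alone, median 0.89, camera adjusted p = 1.04e-15). Of the luminal genes, 18 of 24 rose, 5 fell and 1 was not called (18 and 5 adjusted over the list alone, median 0.46, camera adjusted p = 1.64e-07). Of the immune cell markers, 3 of 4 rose, 0 fell and 1 was not called (3 and 0 adjusted over the list alone, median 2.09, camera adjusted p = 0.382). Over all genes, 6468 genes rose and 4977 fell of 18483 tested, 2337 and 530 of them by at least 2-fold.

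With NOTCHi, the Notch feedback gene Nrarp fell from 75.8 CPM ± 1.96 (SD, n = 3) to 12.6 CPM ± 1.43 (log2 fold change -2.58 ± 0.07, SE, adjusted p = 1.78e-30) and Hey1, a transcriptional repressor downstream of Notch, fell from 2.02 ± 0.314 to 0.278 CPM ± 0.190. Of the Notch targets, 4 of 16 rose, 8 fell and 4 were not called (4 and 8 adjusted over the list alone, median -0.31, mean -0.51 with the test pointing up, camera adjusted p = 0.926). The luminal keratin genes Krt8 and Krt18 fell from 855 ± 44.1 to 277 CPM ± 6.29 and from 504 ± 28 to 121 CPM ± 5.51. Krt5 rose from 6680 ± 234 to 11715 CPM ± 148 and Trp63 from 296 ± 5.39 to 622 CPM ± 9.61. Krt10, a keratin of differentiating squamous cells, fell from 569.7 ± 13.9 to 13.3 CPM ± 0.660. Of the basal genes, 19 of 23 rose, 2 fell and 2 were not called (19 and 2 adjusted over the list alone, median 0.90, camera adjusted p = 2.07e-27). Of the Notch ligands and antagonists, 9 of 10 rose, 0 fell and 1 was not called (9 and 0 adjusted over the list alone, median 1.29, or 0.95 with such genes at their bound, camera adjusted p = 0.000452). Of the hypoxia and glycolysis genes, 2 of 21 rose, 18 fell and 1 was not called (2 and 18 adjusted over the list alone, median -0.63, camera adjusted p = 5.53e-19). Insm1 and Foxa2 held 0 counts with NOTCHi. Of the neuroendocrine genes, 8 of 39 rose, 1 fell and 30 were not called (8 and 0 adjusted over the list alone, median 0.00, mean 0.27 with the test pointing up, camera adjusted p = 0.491). With NOTCHi alone 4810 genes rose and 5173 fell of 18483 tested, 1156 and 992 of them by at least 2-fold. The share of calls that rose was 48.2% with TMM scaling, 54.9% with RLE scaling and 54.9% with DESeq2, so the larger side depends on the scaling.

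With ARi_NOTCHi, Krt18 fell from 504 CPM ± 28 (SD, n = 3) to 38.5 CPM ± 1.52 and the tight junction gene Cldn3 from 85.9 ± 10 to 4.28 CPM ± 0.318. Krt5 rose from 6680 ± 234 to 12526 CPM ± 68.4. The Notch ligand gene Dll1 rose from 22.2 ± 0.471 to 157 CPM ± 3.05. Foxa2 rose from 0 counts to 1.41 CPM ± 0.126, at least 33.4-fold. Of the luminal genes, 3 of 24 rose, 20 fell and 1 was not called (3 and 20 adjusted over the list alone, median -1.42, camera adjusted p = 9.70e-21). Of the hypoxia and glycolysis genes, 21 of 21 fell (0 and 21 adjusted over the list alone, median -2.34, camera adjusted p = 6.77e-71). Egln3 fell from 1097 ± 3.37 to 26.4 CPM ± 1.64. Of the interferon response genes, 2 of 26 rose, 23 fell and 1 was not called (2 and 23 adjusted over the list alone, median -1.02, camera adjusted p = 2.66e-05). Of the neuroendocrine genes, 30 of 39 rose, 0 fell and 9 were not called (30 and 0 adjusted over the list alone, median 4.42, or 2.72 with such genes at their bound, camera adjusted p = 0.000493). Of the amino acid and ER stress genes, 2 of 22 rose, 18 fell and 2 were not called (2 and 18 adjusted over the list alone, median -1.11, camera adjusted p = 2.82e-09). In this arm 6480 genes rose and 6156 fell of 18483 tested, 2581 and 2114 of them by at least 2-fold.

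With ARi_YAPi, Foxa2 rose from 0 counts (n = 3) to 17.6 CPM ± 0.490, at least 419-fold, and the small GTPase gene Rab3c from 0 counts to 20.8 CPM ± 1.36. Cdh2, which encodes N-cadherin, rose from 0 counts to 18.1 CPM ± 0.604. Ccn2 fell from 82.1 ± 2.12 to 1.96 CPM ± 0.245. The secreted chaperone gene Clu rose from 115 ± 7.91 to 625 CPM ± 3.96, and the cornified envelope gene Sprr1b from 6.42 ± 0.704 to 83.8 CPM ± 0.787. Of the neuroendocrine genes, 38 of 39 rose, 0 fell and 1 was not called (38 and 0 adjusted over the list alone, median 7.33, or 5.90 with such genes at their bound, camera adjusted p = 6.86e-28). Of the interferon response genes, 26 of 26 rose (26 and 0 adjusted over the list alone, median 1.15, camera adjusted p = 2.72e-11). Of the hypoxia and glycolysis genes, 21 of 21 fell (0 and 21 adjusted over the list alone, median -2.00, camera adjusted p = 4.30e-86). Of the Notch targets, 13 of 16 rose, 2 fell and 1 was not called (13 and 2 adjusted over the list alone, median 0.90, camera adjusted p = 0.00498, adjusted p = 0.0512 with an estimated correlation). For this pair 7334 genes rose and 5646 fell of 18483 tested, 3280 and 1023 of them by at least 2-fold.

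With YAPi_NOTCHi, Foxa2 rose from 0 counts (n = 3) to 95.2 CPM ± 0.696, at least 2263-fold (adjusted p = 9.14e-42). Insm1 rose from 0.0446 ± 0.0772 to 328 CPM ± 14.4 and Chga, the granule protein chromogranin A, from 0.0584 ± 0.101 to 287 CPM ± 17.1. Rb1 rose from 21.1 ± 2.01 to 119 CPM ± 2.64 (log2 fold change 2.49 ± 0.05, SE), and Mki67, a marker of dividing cells, from 262 ± 11.1 to 397 CPM ± 9.55. Of the cell cycle genes, 6 of 30 rose, 21 fell and 3 were not called (6 and 21 adjusted over the list alone, median -0.42, camera adjusted p = 0.00441). Ccn2 fell from 82.1 ± 2.12 to 0.202 CPM ± 0.0792 and Hes1, a repressor induced by Notch, from 114 ± 2.10 to 34.4 CPM ± 1.15. Among neuroendocrine genes, 38 of 39 rose, 0 fell and 1 was not called (38 and 0 adjusted over the list alone, median 9.99, or 8.36 with such genes at their bound, camera adjusted p = 1.13e-69). Of the Notch ligands and antagonists, 8 of 10 rose, 1 fell and 1 was not called (8 and 2 adjusted over the list alone, median 2.21, camera adjusted p = 9.56e-05), with Dll3 at 11.2 CPM ± 0.0980 against 0 counts. Among hypoxia and glycolysis genes, 21 of 21 fell (0 and 21 adjusted over the list alone, median -2.52, camera adjusted p = 1.16e-71). Of the interferon response genes, 4 of 26 rose, 21 fell and 1 was not called (4 and 21 adjusted over the list alone, median -1.19, camera adjusted p = 3.51e-05). Of the basal genes, 8 of 23 rose and 15 fell (8 and 15 adjusted over the list alone, median -0.42, camera adjusted p = 0.000171). Altogether 7437 genes rose and 6493 fell of 18483 tested, 3814 and 1828 of them by at least 2-fold.

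With COMBO at day 8, Foxa2 rose from 0 counts (n = 3) to 157 CPM ± 2.07, at least 3737-fold, and Chga from 0.0584 ± 0.101 to 484 CPM ± 6.51. Homer2, a synaptic scaffold gene, rose from 22.5 ± 2.36 to 387 CPM ± 4.64. The glucocorticoid-induced kinase gene Sgk1 fell from 602 ± 5.46 to 26.9 CPM ± 0.231 and Car9 from 194 ± 2.73 to 1.27 CPM ± 0.119. Among neuroendocrine genes, 39 of 39 rose (39 and 0 adjusted over the list alone, median 10.76, or 8.97 with such genes at their bound, camera adjusted p = 8.12e-65). Of the interferon response genes, 2 of 26 rose and 24 fell (2 and 24 adjusted over the list alone, median -2.10, camera adjusted p = 1.14e-08). Of the antigen presentation genes, 0 of 14 rose, 13 fell and 1 was not called (0 and 13 adjusted over the list alone, median -1.25, camera adjusted p = 5.05e-05). Of the squamous and wound genes, 1 of 18 rose and 17 fell (1 and 17 adjusted over the list alone, median -1.91, camera adjusted p = 1.22e-11). Of the neuron and glia markers, 7 of 9 rose, 0 fell and 2 were not called (8 and 1 adjusted over the list alone, median 3.68, or 3.40 with such genes at their bound, camera adjusted p = 2.04e-05). Of the cell cycle genes, 6 of 30 rose, 20 fell and 4 were not called (6 and 20 adjusted over the list alone, median -0.36, camera adjusted p = 0.0585). At day 8 of COMBO 7593 genes rose and 7157 fell of 18483 tested, 4183 and 2804 of them by at least 2-fold. The mitochondrial share of counts was 1.33% ± 0.0460 (SD, n = 3) with DMSO, 2.23% ± 0.00404 with ARi, 2.06% ± 0.140 with YAPi, 4.16% ± 0.0748 with COMBO, 3.69% ± 0.101 with ARi_NOTCHi and 3.16% ± 0.0354 with ARi_YAPi.

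Set against YAPi_NOTCHi at the same day, COMBO lowered luminal genes. Psca, a surface protein of prostate epithelium, fell from 470.5 CPM ± 26.3 (SD, n = 3) to 20.1 CPM ± 1.58 and the luminal transcription factor gene Spdef from 18.5 ± 1.52 to 2.75 CPM ± 0.545. Pcsk2, another prohormone convertase, rose from 0.179 ± 0.0754 to 1.28 CPM ± 0.0166. Of the luminal genes, 2 of 24 rose, 19 fell and 3 were not called (2 and 19 adjusted over the list alone, median -0.79, camera adjusted p = 4.10e-35). Among interferon response genes, 2 of 26 rose, 22 fell and 2 were not called (3 and 22 adjusted over the list alone, median -0.97, camera adjusted p = 1.97e-09). Among neuroendocrine genes, 35 of 39 rose, 1 fell and 3 were not called (35 and 1 adjusted over the list alone, median 0.69, camera adjusted p = 8.34e-21). Between these arms 3799 genes rose and 4039 fell of 18483 tested, 555 and 953 of them by at least 2-fold.

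The day 42 arm asks what a longer time on COMBO does. Against day 8, Yap1 fell from 122 CPM ± 4.39 (SD, n = 3) to 0.708 CPM ± 0.122 (log2 fold change -7.42 ± 0.08, SE, adjusted p = 1.04e-46), Krt5 from 3913 ± 80.5 to 0.163 CPM ± 0.199 and Notch1 from 98.0 ± 1.32 to 1.19 CPM ± 0.387. Chga rose from 484 ± 6.51 to 1946 CPM ± 71.0 and Syp, a synaptic vesicle gene, from 62.4 ± 1.59 to 249 CPM ± 2.60. Syt4, another vesicle gene, rose from 2.74 ± 0.825 to 67.6 CPM ± 4.45. Of the basal genes, 1 of 23 rose and 22 fell (1 and 22 adjusted over the list alone, median -7.36, camera adjusted p = 2.19e-90). Of the YAP/TEAD targets, 5 of 21 rose, 15 fell and 1 was not called (5 and 15 adjusted over the list alone, median -1.87, camera adjusted p = 8.75e-09). Of the extracellular matrix genes, 2 of 25 rose, 20 fell and 3 were not called (2 and 20 adjusted over the list alone, median -2.97, camera adjusted p = 1.15e-17). Among neuroendocrine genes, 36 of 39 rose, 1 fell and 2 were not called (36 and 1 adjusted over the list alone, median 1.44, camera adjusted p = 1.97e-24). Of the cell cycle genes, 28 of 30 rose, 1 fell and 1 was not called (28 and 1 adjusted over the list alone, median 0.48, camera adjusted p = 3.86e-05). Of the cholesterol synthesis genes, 20 of 21 rose and 1 fell (20 and 1 adjusted over the list alone, median 0.67, camera adjusted p = 2.42e-08). Of the neuron and glia markers, 7 of 9 rose, 0 fell and 2 were not called (7 and 0 adjusted over the list alone, median 2.13, or 1.54 with such genes at their bound, camera adjusted p = 5.49e-07). Of the fibroblast markers, 0 of 6 rose, 4 fell and 2 were not called (0 and 4 adjusted over the list alone, median -1.57, camera adjusted p = 0.00290). Of the immune cell markers, 0 of 4 rose, 3 fell and 1 was not called (0 and 3 adjusted over the list alone, median -3.94, camera adjusted p = 0.0651). The mitochondrial share was 2.56% ± 0.149 (SD, n = 3) at day 42. Between the days, 6459 genes rose and 6440 fell of 18483 tested, 2031 and 2723 of them by at least 2-fold.

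Against DMSO, whose libraries are from day 8 only, COMBO at day 42 raised Foxa2 from 0 counts (n = 3) to 187 CPM ± 1.12, at least 4438-fold. Krt5 fell from 6680 ± 234 to 0.163 CPM ± 0.199, Yap1 from 260.0 ± 8.89 to 0.708 CPM ± 0.122, Trp63 from 296 ± 5.39 to 0.0225 CPM ± 0.0196 and Myc from 78.1 ± 3.92 to 4.18 CPM ± 0.562. Rb1 rose from 21.1 ± 2.01 to 169 CPM ± 7.18. Among neuroendocrine genes, 39 of 39 rose (39 and 0 adjusted over the list alone, median 11.99, or 10.79 with such genes at their bound, camera adjusted p = 5.40e-59). Of the basal genes, 0 of 23 rose, 22 fell and 1 was not called (0 and 22 adjusted over the list alone, median -7.44, camera adjusted p = 5.03e-45). Of the squamous and wound genes, 18 of 18 fell (0 and 18 adjusted over the list alone, median -9.46, or -7.82 with such genes at their bound, camera adjusted p = 7.84e-17). Of the antigen presentation genes, 14 of 14 fell (0 and 14 adjusted over the list alone, median -2.69, camera adjusted p = 1.14e-06). Of the YAP/TEAD components, 6 of 14 rose, 7 fell and 1 was not called (6 and 7 adjusted over the list alone, median -0.33, camera adjusted p = 0.000580). Of the neuron and glia markers, 8 of 9 rose, 0 fell and 1 was not called (8 and 0 adjusted over the list alone, median 5.22, or 3.74 with such genes at their bound, camera adjusted p = 1.01e-07). Of the immune cell markers, 0 of 4 rose, 3 fell and 1 was not called (0 and 3 adjusted over the list alone, median -4.36, camera adjusted p = 0.0384, adjusted p = 0.0623 with an estimated correlation). Here time and treatment change together, and 7618 genes rose and 8006 fell of 18483 tested, 4623 and 4508 of them by at least 2-fold.

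The NEPC lines are set against PRAD organoids with DMSO, a comparison of separate lines in which line and lineage cannot be told apart. Foxa2, with 0 counts in PRAD organoids given DMSO, was 252 CPM ± 2.83 (SD, n = 3) in NEPC-1, 280.0 CPM ± 12.6 in NEPC-2 and 299 CPM ± 6.33 in NEPC-3. Nefl, a neurofilament gene of neurons, was 673 CPM ± 9.21, 4626 CPM ± 43.7 and 2779 CPM ± 75.6 in that order, and 0 counts in DMSO. Krt5 was 0.260 CPM ± 0.451, 0 counts and 0.0202 CPM ± 0.0349 against 6680 CPM ± 234. Yap1 was below 1 CPM in every line, at 0.888 CPM ± 0.166, 0.521 CPM ± 0.188 and 0.898 CPM ± 0.295.

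Among neuroendocrine genes, 38 of 39 were higher, 0 lower and 1 was not called (38 and 0 adjusted over the list alone, median 11.63, or 10.24 with such genes at their bound, camera adjusted p = 6.24e-55) in NEPC-1. In NEPC-2, 37 of 39 were higher, 0 lower and 2 were not called (37 and 0 adjusted over the list alone, median 11.93, or 10.53 with such genes at their bound, camera adjusted p = 3.50e-50). In NEPC-3, 39 of 39 were higher (39 and 0 adjusted over the list alone, median 11.79, or 10.60 with such genes at their bound, camera adjusted p = 1.39e-48). Basal genes were lower in each line: 23 of 23 were lower (0 and 23 adjusted over the list alone, median -8.10, camera adjusted p = 5.33e-56) in NEPC-1. In NEPC-2, 23 of 23 were lower (0 and 23 adjusted over the list alone, median -6.22, camera adjusted p = 3.50e-50). In NEPC-3, 23 of 23 were lower (0 and 23 adjusted over the list alone, median -7.97, camera adjusted p = 1.75e-58). For neuron and glia markers in NEPC-1, 7 of 9 were higher, 1 lower and 1 was not called (7 and 1 adjusted over the list alone, median 8.40, or 5.88 with such genes at their bound, camera adjusted p = 9.68e-10). For those in NEPC-2, 8 of 9 were higher, 0 lower and 1 was not called (8 and 0 adjusted over the list alone, median 8.85, or 5.55 with such genes at their bound, camera adjusted p = 3.41e-13). For those in NEPC-3, 7 of 9 were higher, 1 lower and 1 was not called (7 and 1 adjusted over the list alone, median 8.91, or 6.10 with such genes at their bound, camera adjusted p = 2.46e-12).

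Against PRAD organoids with DMSO, 21 of 26 were higher, 4 lower and 1 was not called (22 and 4 adjusted over the list alone, median 1.19, camera adjusted p = 0.000290) among interferon response genes in NEPC-1. For NEPC-2, 7 of 26 were higher, 18 lower and 1 was not called (7 and 18 adjusted over the list alone, median -1.05, camera adjusted p = 0.0957). For NEPC-3, 3 of 26 were higher and 23 lower (3 and 23 adjusted over the list alone, median -3.40, camera adjusted p = 5.25e-07). Rsad2, an antiviral gene, was 187 CPM ± 2.00 in NEPC-1 against 5.75 CPM ± 0.149 with DMSO. B2m was 19.2 CPM ± 1.06 in NEPC-3 against 311 CPM ± 15.7. Of the p53 targets in NEPC-1, 3 of 20 were higher, 15 lower and 2 were not called (3 and 15 adjusted over the list alone, median -0.68, camera adjusted p = 0.00800). For that list in NEPC-2, 5 of 20 were higher, 14 lower and 1 was not called (5 and 14 adjusted over the list alone, median -0.81, camera adjusted p = 0.00863). For the same list in NEPC-3, 4 of 20 were higher, 13 lower and 3 were not called (4 and 13 adjusted over the list alone, median -0.64, camera adjusted p = 0.00617). In NEPC-1, 7690 genes were higher and 7764 lower of 18483 tested, 4538 and 4112 of them by at least 2-fold. In that order these were 7599, 7901, 4539 and 4336 in NEPC-2 and 7665, 7796, 4450 and 4455 in NEPC-3.

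**Figure D1:**
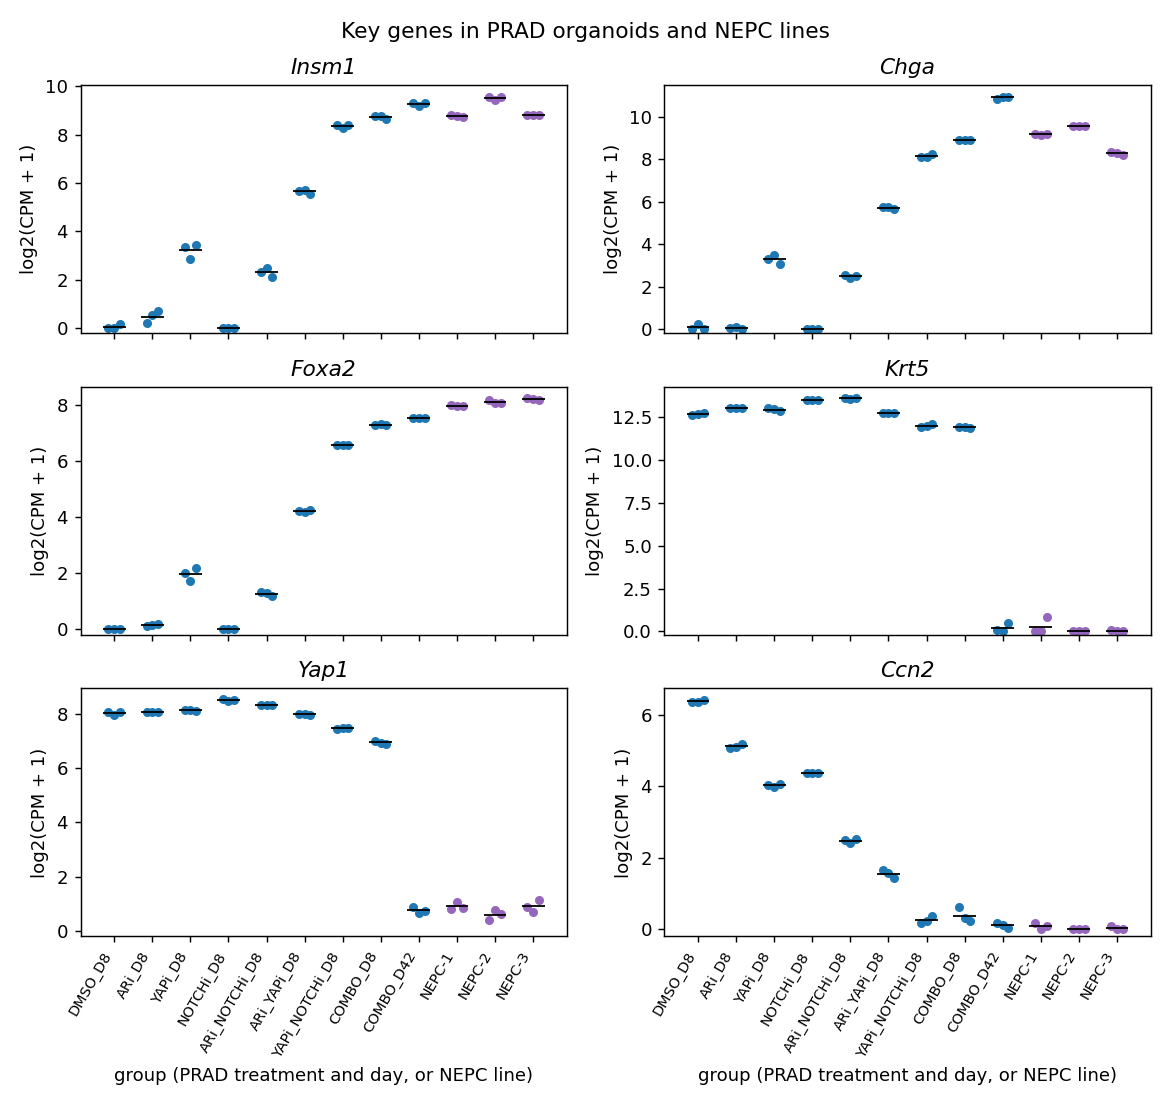
Levels of 6 genes as log2(CPM + 1) on the vertical axis in each of 3 libraries (points, with their mean as a line) of the PRAD groups (blue) and NEPC lines (purple). Insm1, Chga and Foxa2 are near 0 with DMSO and highest in the COMBO and NEPC groups, and Krt5 and Yap1 are near 0 only in COMBO at day 42 and the NEPC lines.

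Set against COMBO at day 42, the mean of the 3 NEPC lines had lower neuroendocrine genes on balance. Neurod1, a proneural transcription factor, was 2.50 CPM ± 0.112 (SD, n = 3) at day 42 and 0.0112 CPM ± 0.0194, 0 counts and 0.0715 CPM ± 0.0495 in the lines. Stmn2, a gene of growing axons, differed by a log2 fold change of -6.95 ± 0.20 (SE) and Nefl by 3.89 ± 0.03. Among neuroendocrine genes, 10 of 39 were higher, 26 lower and 3 were not called (10 and 26 adjusted over the list alone, median -0.35, camera adjusted p = 3.69e-08). Among hypoxia and glycolysis genes, 19 of 21 were higher, 0 lower and 2 were not called (19 and 0 adjusted over the list alone, median 1.45, camera adjusted p = 1.21e-39), and Egln3 was higher by 3.15 ± 0.04. Among interferon response genes, 25 of 26 were higher and 1 lower (25 and 1 adjusted over the list alone, median 2.16, camera adjusted p = 1.39e-08). The mean log2(CPM + 1) of that list was 2.09 ± 0.0201 (SD, n = 3) at day 42, 5.45 ± 0.00359 in NEPC-1, 3.61 ± 0.0197 in NEPC-2 and 1.90 ± 0.0242 in NEPC-3, which lies below day 42. For this contrast 6131 genes were higher and 5868 lower of 18483 tested, 1633 and 1824 of them by at least 2-fold.

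The PRAD arms also allow tests of whether an effect with a pair differs from the sum of the single effects on the log2 scale. Foxa2 was 0 counts with DMSO, 2.99 CPM ± 0.627 (SD, n = 3) with YAPi, 0 counts with NOTCHi and 95.2 CPM ± 0.696 with both. Insm1 was 0.0446 CPM ± 0.0772, 8.46 CPM ± 1.99, 0 counts and 328 CPM ± 14.4 in the same order. For Foxa2 the test against the sum did not pass (adjusted p = 1.00), and its fitted fold rests on groups of 0 counts. Egln3 was lower than the sum, with a log2 difference of -4.32 ± 0.05 (SE), as was Ccn2, with -4.16 ± 0.25. Of the cell cycle genes, 29 of 30 were higher, 0 lower and 1 was not called (29 and 0 adjusted over the list alone, median 1.46, camera adjusted p = 2.32e-34). Among basal genes, 23 of 23 were lower (0 and 23 adjusted over the list alone, median -1.51, camera adjusted p = 1.09e-45). Among hypoxia and glycolysis genes, 21 of 21 were lower (0 and 21 adjusted over the list alone, median -2.06, camera adjusted p = 1.12e-70). Among neuroendocrine genes, 17 of 39 were higher, 0 lower and 22 were not called (17 and 0 adjusted over the list alone, median 4.77, camera adjusted p = 0.0661). For YAPi by NOTCHi 5205 genes were higher and 5701 lower of 18483 tested, 2113 and 2048 of them by at least 2-fold. The share higher was 47.7% with TMM, 40.9% with RLE and 42.6% with DESeq2.

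For ARi by YAPi, Ccn1 and Ccn2 were lower than the sum, with log2 differences of -1.54 ± 0.26 (SE) and -1.68 ± 0.15. Foxa2 was 0 counts with DMSO, 0.109 CPM ± 0.0377 (SD, n = 3) with ARi, 2.99 CPM ± 0.627 with YAPi and 17.6 CPM ± 0.490 with both, and its test did not pass (adjusted p = 0.223). Of the YAP/TEAD targets, 4 of 21 were higher, 14 lower and 3 were not called (4 and 14 adjusted over the list alone, median -0.62, camera adjusted p = 6.09e-12). Of the fibroblast markers, 0 of 6 were higher, 4 lower and 2 were not called (0 and 5 adjusted over the list alone, median -2.07, camera adjusted p = 4.99e-05). In this test 3545 genes were higher and 3219 lower of 18483 tested, 548 and 464 of them by at least 2-fold, and the share of calls that were higher was 52.4% with TMM, 44.7% with RLE and 45.1% with DESeq2. For ARi by NOTCHi, Notch3, a Notch receptor gene, was lower than the sum, with a log2 difference of -2.68 ± 0.09 (SE), as was Clu, with -2.54 ± 0.06. Of the luminal genes, 1 of 24 was higher, 21 lower and 2 were not called (1 and 21 adjusted over the list alone, median -1.12, camera adjusted p = 3.45e-47). Of the immune cell markers, 0 of 4 were higher, 2 lower and 2 were not called (0 and 2 adjusted over the list alone, median -0.96, camera adjusted p = 0.0145). In this contrast 3454 genes were higher and 3808 lower of 18483 tested, 720 and 926 of them by at least 2-fold. The share of calls that were higher was 47.6% with TMM scaling, 35.7% with RLE scaling and 36% with DESeq2.

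In the genotype table, PtP and TKO organoids are first set against WT organoids without agents. Oas2 and Oasl2, interferon-induced antiviral genes, were higher in PtP than in WT organoids, at 16.8 CPM ± 0.391 (SD, n = 3) against 0.225 CPM ± 0.129 and 134 CPM ± 1.01 against 3.84 CPM ± 0.639. Olfm4, a secreted glycoprotein of epithelial progenitors, was 66.9 CPM ± 0.756 against 0 counts. The squamous gene Krtdap was lower, at 0.409 CPM ± 0.152 against 28.7 CPM ± 1.60. Among interferon response genes, 26 of 26 were higher (26 and 0 adjusted over the list alone, median 2.85, camera adjusted p = 2.82e-51). Of the antigen presentation genes, 14 of 14 were higher (14 and 0 adjusted over the list alone, median 1.75, camera adjusted p = 9.36e-22). Among basal genes, 23 of 23 were lower (0 and 23 adjusted over the list alone, median -1.19, camera adjusted p = 9.06e-63). Of the p53 targets, 3 of 20 were higher, 16 lower and 1 was not called (3 and 16 adjusted over the list alone, median -0.55, camera adjusted p = 3.23e-12). Of the luminal genes, 19 of 24 were higher, 4 lower and 1 was not called (19 and 4 adjusted over the list alone, median 0.68, camera adjusted p = 6.82e-13). Among immune cell markers, 4 of 4 were higher (4 and 0 adjusted over the list alone, median 3.06, or 1.70 with such genes at their bound, camera adjusted p = 0.00533, adjusted p = 0.0813 with an estimated correlation). For PtP against WT 5543 genes were higher and 5685 lower of 18430 tested, 1732 and 1034 of them by at least 2-fold.

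In TKO organoids, Oas2 was 27.8 CPM ± 0.177 (SD, n = 3), and Cd74, the class II invariant chain, was 5.09 CPM ± 0.252 against 0.126 CPM ± 0.0457 in WT. Krt13, a squamous keratin gene, was 41.4 CPM ± 1.28 against 737 CPM ± 5.44. Among interferon response genes, 26 of 26 were higher (26 and 0 adjusted over the list alone, median 3.56, camera adjusted p = 4.79e-69). Among basal genes, 23 of 23 were lower (0 and 23 adjusted over the list alone, median -1.48, camera adjusted p = 2.64e-72). Among immune cell markers, 4 of 4 were higher (4 and 0 adjusted over the list alone, median 3.65, or 1.82 with such genes at their bound, camera adjusted p = 0.00857, adjusted p = 0.0911 with an estimated correlation). For TKO against WT 5998 genes were higher and 5604 lower of 18430 tested, 1994 and 1026 of them by at least 2-fold. Between TKO and PtP organoids the differences were smaller. Mcm6, a replication helicase gene, was 223 CPM ± 6.19 in TKO and 121 CPM ± 1.97 in PtP organoids, and the growth factor receptor gene Fgfr1 was 3.22 CPM ± 0.301 and 0.315 CPM ± 0.196. Among cell cycle genes, 30 of 30 were higher (30 and 0 adjusted over the list alone, median 0.32, camera adjusted p = 7.58e-55). For TKO against PtP 2422 genes were higher and 2473 lower of 18430 tested, 170 and 44 of them by at least 2-fold. Of these calls, 49.5% were higher with TMM, 43.0% with RLE and 42.6% with DESeq2.

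The treated arms ask whether YAPi_NOTCHi and COMBO act alike in the 3 genotypes. With YAPi_NOTCHi, Insm1 rose from 0 counts to 28.9 CPM ± 1.83 (SD, n = 3) in WT, from 0.0474 CPM ± 0.0466 to 46.2 CPM ± 2.97 in PtP and from 0.126 CPM ± 0.0339 to 254 CPM ± 8.86 in TKO organoids. Mki67 fell from 128 CPM ± 4.38 to 1.49 CPM ± 0.181 in WT and from 119.6 CPM ± 7.12 to 18.5 CPM ± 0.487 in PtP organoids. In TKO organoids Mki67 was 174 CPM ± 4.92 and 168 CPM ± 3.45. Ccn2 fell from 128 CPM ± 3.67 to 0.114 CPM ± 0.0834 in WT organoids. In WT organoids Chga rose from 0 counts to 62.5 CPM ± 1.91, at least 1183-fold, and Dclk1, a tuft cell kinase gene, from 0.0374 ± 0.0325 to 14.9 CPM ± 0.245. Of the tuft cell genes, 10 of 11 rose and 1 fell (10 and 1 adjusted over the list alone, median 3.85, camera adjusted p = 0.114). Of the neuroendocrine genes in WT organoids 36 of 39 rose, 1 fell and 2 were not called (36 and 1 adjusted over the list alone, median 6.59, or 5.69 with such genes at their bound, camera adjusted p = 1.98e-11). Among cell cycle genes, 30 of 30 fell (0 and 30 adjusted over the list alone, median -4.85, camera adjusted p = 6.88e-43). Among hypoxia and glycolysis genes, 0 of 21 rose, 20 fell and 1 was not called (0 and 20 adjusted over the list alone, median -3.27, camera adjusted p = 2.84e-62). In WT organoids 8378 genes rose and 7411 fell of 18430 tested, 5254 and 3147 of them by at least 2-fold.

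In PtP organoids with YAPi_NOTCHi, Pcsk1 rose from 0 counts (n = 3) to 84.4 CPM ± 1.42, at least 1849-fold. Pbsn, the prostate secretory gene probasin, rose from 0 counts to 23.9 CPM ± 1.45. Among neuroendocrine genes, 37 of 39 rose, 1 fell and 1 was not called (37 and 1 adjusted over the list alone, median 7.01, or 6.31 with such genes at their bound, camera adjusted p = 5.35e-19). Among cell cycle genes, 30 of 30 fell (0 and 30 adjusted over the list alone, median -2.98, camera adjusted p = 1.64e-29). Of the cholesterol synthesis genes, 21 of 21 fell (0 and 21 adjusted over the list alone, median -1.73, camera adjusted p = 1.15e-34). In PtP organoids 8284 genes rose and 7478 fell of 18430 tested, 4874 and 2752 of them by at least 2-fold. In TKO organoids with YAPi_NOTCHi, Pcsk1 rose from 0 counts to 334 CPM ± 0.345, at least 8435-fold, Rb1 from 22.9 ± 0.483 to 61 CPM ± 2.69 and Ccne2, a cyclin of S phase entry, from 24.3 ± 1.94 to 112.1 CPM ± 1.09. Ccnd1, cyclin D1, fell from 761 ± 7.72 to 10 CPM ± 0.889. Among neuroendocrine genes, 39 of 39 rose (39 and 0 adjusted over the list alone, median 8.35, or 8.10 with such genes at their bound, camera adjusted p = 2.69e-49). Among cell cycle genes, 8 of 30 rose, 19 fell and 3 were not called (8 and 19 adjusted over the list alone, median -0.34, camera adjusted p = 0.388). Of the YAP/TEAD targets, 3 of 21 rose and 18 fell (3 and 18 adjusted over the list alone, median -2.58, camera adjusted p = 9.60e-16). In TKO organoids 8418 genes rose and 7483 fell of 18430 tested, 4951 and 2776 of them by at least 2-fold.

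With COMBO, Insm1 reached 66.2 CPM ± 3.15 (SD, n = 3) in WT, 122 CPM ± 2.89 in PtP and 402 CPM ± 39.3 in TKO organoids. Mki67 was 1.45 CPM ± 0.268, 8.16 CPM ± 0.241 and 319 CPM ± 8.32 in the same order. In WT organoids Fkbp5 fell from 90.5 ± 3.81 to 5.39 CPM ± 0.355 and Nrarp from 292 ± 19.9 to 3.41 CPM ± 0.328. Among neuroendocrine genes, 37 of 39 rose, 0 fell and 2 were not called (37 and 0 adjusted over the list alone, median 7.58, or 6.36 with such genes at their bound, camera adjusted p = 5.39e-20) in WT organoids. In PtP organoids, 38 of 39 rose, 0 fell and 1 was not called (38 and 0 adjusted over the list alone, median 8.79, or 7.67 with such genes at their bound, camera adjusted p = 2.36e-38). Among cell cycle genes, 30 of 30 fell (0 and 30 adjusted over the list alone, median -4.87, camera adjusted p = 2.15e-41) in WT organoids. In PtP organoids, 30 of 30 fell (0 and 30 adjusted over the list alone, median -3.69, camera adjusted p = 1.44e-37). In WT organoids 8280 genes rose and 7527 fell of 18430 tested, 5127 and 3081 of them by at least 2-fold. In PtP organoids 8254 genes rose and 7411 fell of 18430 tested, 4925 and 2600 of them by at least 2-fold.

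In TKO organoids with COMBO, Mmp7, a matrix metalloproteinase gene, fell from 1985 CPM ± 2.62 (SD, n = 3) to 4.54 CPM ± 0.345 and Ccnd1 from 761 ± 7.72 to 4.28 CPM ± 0.0986. Snap25, a gene of vesicle fusion, rose from 0.0164 ± 0.0283 to 261 CPM ± 7.34. Among neuroendocrine genes, 39 of 39 rose (39 and 0 adjusted over the list alone, median 9.88, or 8.89 with such genes at their bound, camera adjusted p = 5.09e-16, adjusted p = 0.154 with an estimated correlation). For cell cycle genes, 19 of 30 rose, 7 fell and 4 were not called (19 and 7 adjusted over the list alone, median 0.26, camera adjusted p = 0.0690). Among interferon response genes, 1 of 26 rose, 24 fell and 1 was not called (1 and 24 adjusted over the list alone, median -2.79, camera adjusted p = 1.01e-08, adjusted p = 0.154 with an estimated correlation). Replicate 1 of this group holds 92280307 counts. In these organoids 8508 genes rose and 7553 fell of 18430 tested, 4917 and 2846 of them by at least 2-fold.

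**Figure D2:**
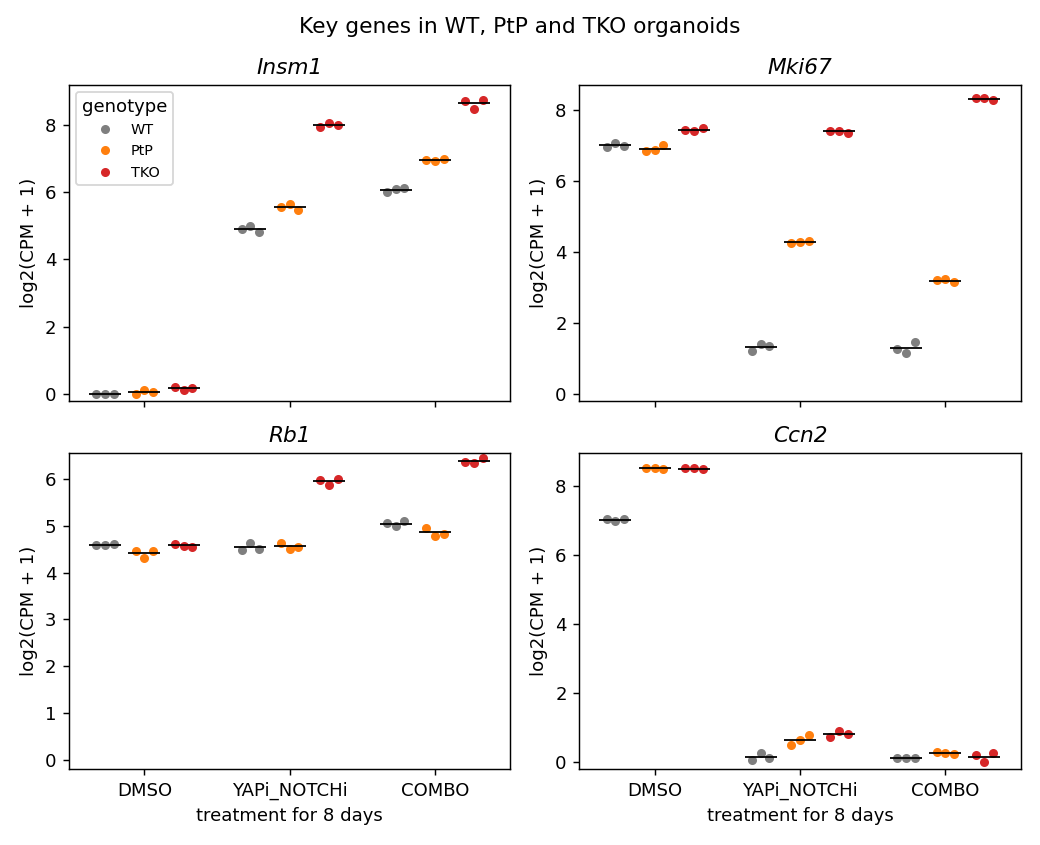
Levels of 4 genes as log2(CPM + 1) on the vertical axis in each of 3 libraries (points, with their mean as a line) by treatment for WT, PtP and TKO organoids. With YAPi_NOTCHi and COMBO, Mki67 is lower than with DMSO in each WT and PtP library, and Rb1 is higher in each TKO library.

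The difference between genotypes in the effect of an agent was tested itself. For YAPi_NOTCHi, the effect on Ccnb1, a mitotic cyclin gene, was higher in TKO than in WT organoids by a log2 difference of 9.09 ± 0.13 (SE, adjusted p = 2.02e-40), and that on Mki67 by 6.34 ± 0.08. The effect on Rb1 was higher by 1.45 ± 0.08. Olfm4 was 0 counts with DMSO and 29.1 CPM ± 0.633 with YAPi_NOTCHi in WT organoids, and 120.0 CPM ± 2.96 and 232 CPM ± 4.70 in TKO organoids. The effect on Dclk1 was lower in TKO organoids, by a difference of -8.53 ± 0.34. Of the cell cycle genes, the effect was higher for 30 of 30 (30 and 0 adjusted over the list alone, median 4.95, camera adjusted p = 2.42e-82). Of the antigen presentation genes it was lower for 14 of 14 (0 and 14 adjusted over the list alone, median -2.05, camera adjusted p = 2.73e-15). Of the tuft cell genes it was lower for 11 of 11 (0 and 11 adjusted over the list alone, median -4.68, camera adjusted p = 0.0331, adjusted p = 0.119 with an estimated correlation). Between PtP and WT organoids, the effect on Calm4, a calmodulin-like gene of skin, was higher by 8.97 ± 0.20 and that on Sprr1b by 8.33 ± 0.44. Of the squamous and wound genes, 14 of 17 were higher, 2 lower and 1 was not called (14 and 2 adjusted over the list alone, median 1.55, camera adjusted p = 1.58e-13). For interferon response genes, 1 of 26 was higher, 22 lower and 3 were not called (1 and 22 adjusted over the list alone, median -1.82, camera adjusted p = 8.54e-12). Between TKO and PtP organoids, the effect on Mki67 was higher by 2.65 ± 0.06. For cell cycle genes, 30 of 30 were higher (30 and 0 adjusted over the list alone, median 2.74, camera adjusted p = 6.28e-129). For these 3 tests in the order TKO against WT, PtP against WT and TKO against PtP, 12675, 10584 and 9701 genes passed of 18430. Of these, 5374, 3126 and 2267 differed by at least 2-fold.

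For COMBO, the effect on Ccnb1 was higher in TKO than in WT organoids by 9.50 ± 0.13 (SE, adjusted p = 8.16e-42) and that on Mki67 by 7.33 ± 0.08. Ube2c, the ubiquitin-conjugating enzyme of the anaphase complex, was 85.4 CPM ± 0.131 (SD, n = 3) with DMSO and 0.197 CPM ± 0.0431 with COMBO in WT organoids. In TKO organoids it was 63.6 CPM ± 2.21 and 83.7 CPM ± 0.951. For cell cycle genes, 30 of 30 were higher (30 and 0 adjusted over the list alone, median 5.44, camera adjusted p = 4.58e-86). Of the extracellular matrix genes, 5 of 24 were higher, 17 lower and 2 were not called (5 and 17 adjusted over the list alone, median -1.48, camera adjusted p = 1.63e-06). Between PtP and WT organoids, of the cholesterol synthesis genes, 0 of 21 were higher, 19 lower and 2 were not called (0 and 19 adjusted over the list alone, median -0.66, camera adjusted p = 3.02e-14). For cell cycle genes, 24 of 30 were higher, 2 lower and 4 were not called (24 and 3 adjusted over the list alone, median 1.42, camera adjusted p = 0.000511). Between TKO and PtP organoids, the effect on E2f7, a repressor of the cell cycle, was higher by 5.51 ± 0.18 and that on Fgfr1 lower, by -3.81 ± 0.25. For cell cycle genes, 30 of 30 were higher (30 and 0 adjusted over the list alone, median 3.76, camera adjusted p = 7.82e-165). In the order TKO against WT, PtP against WT and TKO against PtP, 12802, 11023 and 10484 genes passed of 18430, 5686, 3149 and 2880 of them by at least 2-fold.

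Effects in separate tables were set side by side across genes, and genes are not independent replicates. The COMBO effects in PRAD and TKO organoids had Pearson's r = 0.888 (Spearman's rho 0.764) over 17052 genes, and 5520 genes rose in both where 3291 would by chance. Against PtP and WT organoids, they had r = 0.826 (rho 0.682) and r = 0.75 (rho 0.679). For YAPi_NOTCHi, PRAD organoids had r = 0.837 (rho 0.631) with TKO, r = 0.773 (rho 0.609) with PtP and r = 0.678 (rho 0.599) with WT organoids. The difference of suspension from Matrigel in TKOM organoids had r = 0.541 (rho 0.358) over 15303 genes with the difference of NEPC-1 from PRAD organoids with DMSO. With those of NEPC-2 and NEPC-3 it had r = 0.545 (rho 0.361) and r = 0.558 (rho 0.410). It had r = 0.551 (rho 0.368) with the effect of COMBO at day 42. These 10 correlations are the family computed, without a p-value.

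**Figure D3:**
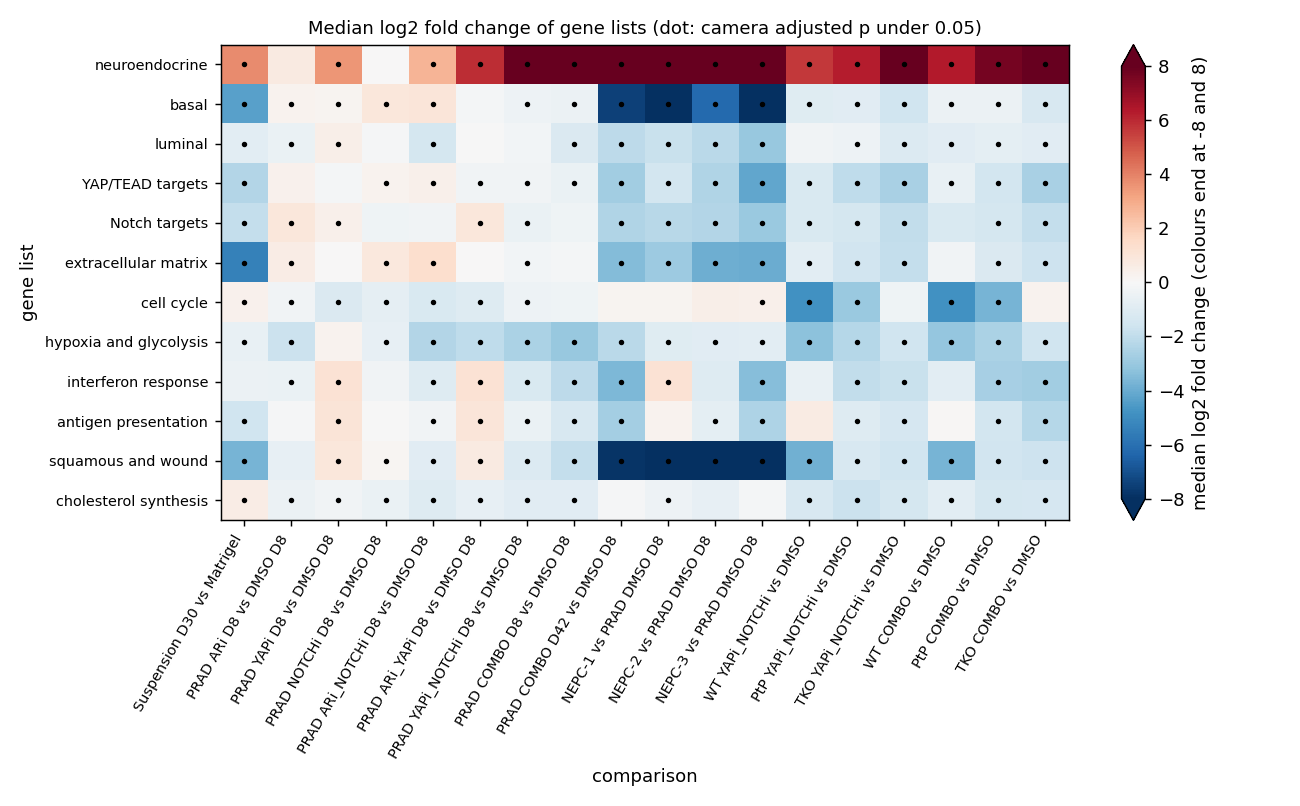
Median log2 fold change (colour, with genes of 0 counts at their bound) of 12 gene lists (vertical axis) in comparisons with Matrigel or DMSO (horizontal axis), with a dot where the camera adjusted p with the preset correlation is under 0.05. The neuroendocrine list is positive and dotted in each column except PRAD with NOTCHi, and the basal list is lowest in COMBO at day 42, the NEPC lines and suspension.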

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

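The tests of library scaling (for both patterns it is set against), of the depth of TKO_COMBO_D8 replicate 1, of RNA from immune cells, of fold changes set against counts near 0 and of reads carried over from other libraries of the lane were chosen only after the result was seen. The tests of other splits of the libraries were planned, although the splits of 14 comparisons had been computed, and not looked at, before their possible outcomes were written down. The comparison of NEPC-1 with NEPC-3 was also chosen after the result was seen.

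The cell cycle list fell more with YAPi_NOTCHi and COMBO in WT than in TKO organoids. Of its 30 genes in TKO organoids, 19 fell and 8 rose with YAPi_NOTCHi (median -0.34), and 7 fell and 19 rose with COMBO (median 0.26). Against library scaling, which moves all genes of a library alike, the median YAPi_NOTCHi effect of the list in TKO minus WT lay 4.96 log2 units above that of all genes, and its lower quartile 2.84 above. Against depth of TKO_COMBO_D8 replicate 1, the median COMBO effect in TKO minus WT was 5.45 without that library, against 5.44 with it. The mitochondrial share of counts also differed with the agents. It was 0.925% ± 0.00242 (SD, n = 3) with DMSO, 5.95% ± 0.127 with YAPi_NOTCHi and 5.12% ± 0.169 with COMBO in WT organoids. In the same order it was 1.64% ± 0.0161, 6.81% ± 0.160 and 4.70% ± 0.134 in PtP organoids, and 1.38% ± 0.0323, 5.26% ± 0.0917 and 3.27% ± 0.0775 in TKO organoids. The state of the cells or of the RNA stays open and untested, as do the genotype that the labels name and the growth state at harvest.

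The interferon response list was higher in NEPC-1 than in NEPC-3, with summed levels of 2016 CPM ± 17.4 and 167 CPM ± 0.927 (SD, n = 3). Against RNA from immune cells, the 5 measured genes of the immune list sum to 2.52 CPM ± 0.0313 in NEPC-1, which is 0.136% of the gain of 1849 CPM. The most abundant of them, Itgam, was 0.889 CPM ± 0.281 in NEPC-1, and 2 of the 5 reach 1 CPM in PRAD organoids with DMSO. Against library scaling, the median log2 difference of the list lay 4.65 above that of all genes, and its lower quartile 3.15 above. The line itself and its passage or culture history stay open and untested.

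In PRAD organoids, neuroendocrine genes were higher with YAPi than with DMSO, and higher with YAPi_NOTCHi than with either alone. For fold changes set against counts near 0, 36 of 39 measured genes (92.3%) lay higher in every YAPi_NOTCHi library than the highest YAPi library plus the highest NOTCHi library in CPM. NOTCHi levels are near 0 for many of them, so this restates the pattern. For reads carried over from other libraries of the lane, the median level with DMSO was 0.971% of that in YAPi replicates 2 and 3 on the same lane, over 35 genes. Carry-over shared evenly by a lane would make these levels alike. A lower level with DMSO is the pattern itself, so this share restates it and cannot decide on carry-over. Carry-over, even or uneven, stays open. The mitochondrial share was 1.33% ± 0.0460 (SD, n = 3) with DMSO, 2.06% ± 0.140 with YAPi, 2.44% ± 0.0298 with NOTCHi and 3.42% ± 0.107 with both, so the state of the cells or of the RNA is open as well. The treatment itself and a change in the share of cell types stay open and untested.

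Effects that differed between groups by their own test were looked at again. In PRAD organoids the edgeR test passed for 10906 genes for YAPi by NOTCHi, 6764 for ARi by YAPi and 7262 for ARi by NOTCHi. Among lists with at least 10 measured genes that were called with both the preset and the estimated correlation, the largest median difference was that of the squamous and wound list for YAPi by NOTCHi, at -2.33. It was that of the YAP/TEAD targets for ARi by YAPi, at -0.62, and of the luminal list for ARi by NOTCHi, at -1.12. For YAPi_NOTCHi, 12675, 10584 and 9701 genes passed for TKO minus WT, PtP minus WT and TKO minus PtP, and the cell cycle list had the largest medians, 4.95, 2.23 and 2.74. For COMBO, 12802, 11023 and 10484 genes passed in that order. The cell cycle list had medians of 5.44 for TKO minus WT and 3.76 for TKO minus PtP, and the interferon response list had -1.69 for PtP minus WT.

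For 23 comparisons of 2 groups of 3 libraries, the 10 splits of the 6 libraries are too few for a share under 0.05. These fits hold only the groups compared, so the counts differ a little from those of the report. The real split of suspension against Matrigel gave 12140 genes that passed with edgeR. Against PRAD organoids with DMSO, ARi gave 9740, YAPi 10524, NOTCHi 9404, ARi_NOTCHi 11886, ARi_YAPi 12310, YAPi_NOTCHi 12990 and COMBO 14013. Against those, COMBO at day 42, NEPC-1, NEPC-2 and NEPC-3 gave 14671, 14730, 14637 and 14708. In PRAD organoids, COMBO gave 7858 against YAPi_NOTCHi and, at day 42, 12351 against day 8. YAPi_NOTCHi against DMSO gave 14735 in WT, 14789 in PtP and 15276 in TKO organoids. COMBO against DMSO gave 14843, 14817 and 15526 in that order. With DMSO, PtP against WT gave 10501, TKO against WT 11018 and TKO against PtP 4787. In each of these comparisons the highest of the other splits gave 0 genes, with 9 to 408 at an unadjusted p under 0.05 as the highest counts, and the real split was the 1 split with as many genes.

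In the other comparisons, which hold 4 groups of 3 libraries, 100 splits were drawn with the real one included. For NEPC mean of 3 lines vs PRAD COMBO D42 the real split gave 11743 genes and the highest other 3961, and 1 of 100 splits gave as many. For each PRAD interaction, 1 of 100 splits gave as many. The real split and the highest other gave 10589 and 2919 genes for YAPi by NOTCHi. They gave 6677 and 2406 for ARi by YAPi and 7215 and 1135 for ARi by NOTCHi. For the YAPi_NOTCHi effects PtP minus WT, TKO minus WT and TKO minus PtP, the real split gave 10308, 12565 and 9671 genes. The highest other gave 13035, 11818 and 6191, and 2, 1 and 1 of 100 splits gave as many. For the COMBO effects in that order, the real split gave 10830, 12777 and 10471 genes. The highest other gave 4878, 14311 and 6334, and 1, 2 and 1 of 100 splits gave as many. For the YAPi_NOTCHi effects of PtP minus WT and TKO minus WT and for the COMBO effect of TKO minus WT, the highest other split set the 6 treated libraries against the 6 with DMSO. For PRAD YAPi by NOTCHi it set DMSO and YAPi against NOTCHi and YAPi_NOTCHi, and for the NEPC contrast NEPC-2 against the rest. Such splits follow treatment or line, which are structures of the samples and not a technical batch. The median other split gave 0 genes in each comparison. Splits that mix groups put the differences between groups into the spread. The shares therefore do not test the difference of effects by itself.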

How the results depend on the processing

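The alternatives that leave out the libraries that stand apart and that thin the deepest libraries were chosen only after the result was seen, and the others were planned. The gene counts of the 33 comparisons stayed within 1.5 times under each alternative run for them. These were RLE size factors, no filter, DESeq2, the replicate block, only the groups compared (for 32 of them, since the TKOM table holds no other group) and 258 fits without a replicate. The farthest from 1 was TKO against PtP organoids with DMSO, with 3929 genes without TKO_DMSO_D8 replicate 2 against 4895 with it. The median shift of all genes between RLE and TMM lay between -0.09 and 0.08. The larger side of the calls turned in 13 comparisons with RLE and 13 with DESeq2, while 0 genes called with both TMM and RLE changed sign.

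Replicate numbers did not pair the libraries: in 0 of 1, 66 and 36 pairs of groups in the TKOM, PRAD and NEPC, and genotype tables did all same-numbered libraries correlate over 0.1 after group means were removed. With the replicate block, PRAD COMBO D8 vs DMSO D8 had 14706 genes against 14750, and a paired design is not given in the labels. PRAD_NOTCHi_D8 replicate 2 stands apart from the other libraries of its group, and PRAD_YAPi_D8 replicate 1 and TKO_COMBO_D8 replicate 1 are the deepest. Without the libraries that stand apart, PRAD NOTCHi D8 vs DMSO D8 had 9467 genes against 9983, PRAD YAPi D8 vs DMSO D8 had 10804 against 11445 and TKO COMBO vs DMSO had 15548 against 16061. Thinning the deepest libraries gave 11278 and 15811 genes for those last comparisons.

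Of 792 tests of a list in a comparison, 462 were called by camera with the preset correlation. RLE size factors called 467, with 6 lost and 11 gained, and the replicate block called 463, with 6 lost and 7 gained. An estimated correlation called 344, with 120 lost and 2 gained, and each list call that the report gives and that was lost has its adjusted p there. Fry, which does not compare a list with other genes, called 746.

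Pearson's r across tables rose when fewer genes were used. Spearman's rho rose over genes called in both, and fell in each pair over genes with an average log2 CPM of at least 3, where it was 0.328 to 0.702. For COMBO in PRAD organoids against WT, PtP and TKO organoids r was 0.810, 0.867 and 0.912 over genes called in both, and 0.794, 0.847 and 0.903 over genes with an average log2 CPM of at least 3 in both. For YAPi_NOTCHi in that order it was 0.753, 0.835 and 0.876, and 0.741, 0.808 and 0.851. For suspension against NEPC-1, NEPC-2, NEPC-3 and COMBO at day 42 it was 0.585, 0.587, 0.596 and 0.593, and 0.588, 0.576, 0.601 and 0.584. Of the genes named with a comparison, Insm1, PRAD YAPi by NOTCHi interaction, no longer passed without PRAD_DMSO_D8 replicate 3 (adjusted p = 1.00, against 0.00475 with it), since the other libraries with DMSO hold 0 counts of it. Under its other alternatives the adjusted p was 6.09e-07 to 0.00813. Foxa2, PRAD YAPi by NOTCHi interaction, passed with DESeq2 (adjusted p = 0.00773, against 1.00 under each of its other alternatives). The others kept their call and direction under each alternative run.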

Other observations

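The gene tests in this part were planned, while the chi-square values come from a check of replicates that the plan did not name. Sox2, a transcription factor of stem and neuroendocrine cells, rose with COMBO and in suspension. It went from 30.2 CPM ± 2.14 (SD, n = 3) to 118 CPM ± 3.82 in PRAD organoids at day 8, and was 248 CPM ± 2.83 in NEPC-1, 285 CPM ± 5.51 in NEPC-2 and 164 CPM ± 5.03 in NEPC-3. In TKO organoids COMBO raised it from 53.8 CPM ± 0.847 to 115 CPM ± 2.23. In TKOM organoids it was 30.9 CPM ± 0.805 in Matrigel and 122 CPM ± 2.48 in suspension. Vim, the mesenchymal filament gene vimentin, rose with COMBO in PRAD organoids from 0.597 CPM ± 0.163 to 21.2 CPM ± 1.11 at day 8 and fell to 2.56 CPM ± 0.615 at day 42. In WT organoids COMBO lowered Vim from 2.29 CPM ± 0.367 to 0.0914 CPM ± 0.0898. Ankrd1, a target of YAP and TEAD, fell from 1.52 CPM ± 0.163 to 0 counts with YAPi, while with ARi it was 1.56 CPM ± 0.291 (not called). A low level was not particular to YAPi, since Ankrd1 was 0.059 CPM ± 0.063 with NOTCHi and 0.055 CPM ± 0.064 with ARi_NOTCHi.

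Pou2f3, the transcription factor of tuft cells, rose with COMBO in WT organoids from 0.252 CPM ± 0.0915 (SD, n = 3) to 4.17 CPM ± 0.278 and in PtP organoids from 1.02 CPM ± 0.455 to 3.85 CPM ± 0.287. In TKO organoids it was 1.33 CPM ± 0.253 with DMSO and 1.16 CPM ± 0.121 with COMBO (not called). In PRAD organoids its highest level was 2.47 CPM ± 0.209 with ARi_NOTCHi, against 0.0551 CPM ± 0.0189 with DMSO. Ezh2, a histone methyltransferase of dividing cells, fell with COMBO in WT organoids from 87.1 CPM ± 5.54 to 44.3 CPM ± 1.17 and rose in PRAD organoids from 87.0 CPM ± 6.80 to 118 CPM ± 2.83, where 20 of 30 cell cycle genes fell and 6 rose (median -0.36).

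Replicate 2 of PRAD_NOTCHi_D8 differs from the rest of its group. Chi-square per degree of freedom between replicates 1 and 2 was 24.7, between replicates 2 and 3 23.3 and between replicates 1 and 3 2.58, while the highest value in another group was 12. Replicate 1 of PRAD_YAPi_D8 holds 77790816 counts and its library code names another lane than the rest of its table. Replicate 1 of TKO_COMBO_D8 holds 92280307.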
